A study of Homo sapiens with 12 samples.

How the data were processed

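RNA of the A375 and CHL1 melanoma cell lines and of their palbociclib-resistant derivatives was sequenced from total RNA in 12 libraries, 3 in each of 4 groups, with a kit that does not mark the strand. The deposited files are 2 tables, 1 per line, of read counts per Ensembl gene for 6 libraries each, and the values are whole numbers without normalisation. The submitters' processing notes name CASAVA 1.8.2, cutadapt 1.7, TopHat2, HTSeq 0.5 and limma. The genome build and the annotation behind the counts are not given in the sources used here, so no coordinates are printed. The tables list 33932 genes for A375 and 32478 for CHL1, 29735 in both, and neither lists a gene with 0 counts in all of its libraries. Gene symbols were added from a table of names and from GENCODE release 29, which also gave the gene types and the order along chromosomes. No symbol was found for 2484 identifiers with 1.62% of the counts in A375 and for 2284 with 1.38% in CHL1. Reads of overlapping genes on opposite strands, and of gene families with near-identical copies, may be assigned to the wrong gene.

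Total counts ran from 25398920 to 29812686 per library. A floor of 3 counts per library stood for 0.101 to 0.118 CPM. Intervals and floors cover counting error only, since reads without molecular identifiers are not independent molecules. Groups were taken from the sample labels, and all 12 columns were used.

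Each line was tested on its own in R 4.3.3 with edgeR 4.0.16, with TMM factors, filterByExpr at its defaults (minimum count 10) and the quasi-likelihood F-test of resistant against parental. A gene was called at a Benjamini-Hochberg adjusted p below 0.05, and a second count required a fold change of at least 2. All p-values are two-sided. The difference between lines was the interaction term of a fit to all 12 libraries over genes in both tables. Overlaps of the calls were compared with independence by Fisher's exact test, and fold changes were correlated across genes. Normalised CPM used the TMM factors.

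Gene lists were tested with camera in limma 3.58.1 on voom values with a preset inter-gene correlation of 0.01, adjusted over the lists with at least 5 measured members. The estimated correlation, fry and ranks were alternatives, and fry asks whether a list moves one way without comparing it with other genes. The 39 lists covered the CDK4/6-RB axis, G1/S and DNA replication, G2/M and mitosis, p53 targets, the PRMT family and PRMT5 partners, the spliceosome core, MITF and pigment cell genes, the dedifferentiated melanoma state, MAPK pathway output and receptor tyrosine kinases. Further lists were drug efflux transporters, the lysosome, cholesterol synthesis and uptake, the interferon response, MHC class I and class II presentation, inflammatory cytokines, the extracellular matrix, TGF-beta targets, hypoxia and glycolysis, ATF4 and amino acid stress, and ER chaperones and UPR. The rest were oxidative phosphorylation, fatty acid synthesis and handling, NRF2 targets, apoptosis regulators, YAP/TAZ targets, WNT and beta-catenin, Notch, neural and axon guidance genes, ribosomal proteins, cytosolic chaperones, immediate-early genes, mitochondrially encoded mRNAs and replication-dependent histones. Markers of keratinocytes and epithelia, fibroblasts, leukocytes and endothelium stood for other cells a culture could hold. The lists, the panel of 18 genes, the tests and the rule for named genes were fixed before the data were examined.

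Genes named in the text were the panel (CDK4, CDK6, CCND1, CCND3, CCNE1, CCNE2, CDKN1A, CDKN1B, CDKN2A, RB1, E2F1, PRMT5, MDM4, MDM2, MITF, SOX10, AXL and MKI67). To these were added the 10 highest and 10 lowest log2 fold changes per line among called genes with at least 10 CPM in the higher group, no overlap between groups and an established symbol. Up to 4 members with the smallest adjusted p were named in each called list. Across lines the rule took 5 genes per direction and 10 in opposite directions among those called at 2-fold in both, and fewer met it. Other genes were named after their values were seen, as ends of blocks, list members or neighbours.

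Neighbouring genes were scanned after the values were seen. Windows of 21 consecutive protein-coding genes of at least 1 CPM were compared with the 95th percentile of the largest absolute window median in 1000 shuffles of the gene order, and overlapping windows past it were joined into blocks. Tested genes that the scan left out, without the protocadherins and without genes that overlap a scanned one, were then compared inside and outside the blocks. This scan, the interval calculations and the figures used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.

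The tests were tried on simulated data with 200 changed genes. In A375 edgeR recovered 60%, 84%, 100% and 100% of genes changed 1.5-, 2-, 4- and 8-fold, and 18 unchanged genes were called (9.47% of calls). In CHL1 it recovered 78%, 98%, 100% and 100%, with 15 unchanged genes called (7.39%). For the difference between lines the values were 50%, 64%, 92% and 100%, with 8 unchanged genes called (4.97%). Camera called both of the 2 lists shifted by 0.4 on the log2 scale and 0 others in each line. With an estimated correlation it also called both. The simulated genes were drawn independently, while the correlation estimated in A375 was 0.624 for G1/S and 0.254 for p53 targets. The simulation therefore says nothing about false list calls in the real data. Its shift was also larger than medians such as 0.157 for G2/M in A375. The scan found 1 block that held all 60 lowered genes plus 22 others in A375 and 20 in CHL1.

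Alternatives were RLE factors, library size without composition factors, no low-count filter, a filter of 1 CPM in 3 libraries, DESeq2 1.42.0, limma-voom, the replicate number as a block, all 12 libraries in 1 fit, an adjusted p of 0.01, a test against a 2-fold change, and each library left out in turn. Restricting the counts to genes outside the blocks was added after the data were seen. Other splits of the libraries were fitted as the real one was.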

Results

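Messenger RNA was sequenced from 2 human melanoma cell lines, A375 and CHL1, and from a derivative of each that had grown resistant to palbociclib, an inhibitor of the cyclin-dependent kinases CDK4 and CDK6. The derivatives arose under rising palbociclib concentrations over 7 months in A375 and 3 months in CHL1, were kept in 4 µM palbociclib, and spent 72 h without the drug before their RNA was taken. Each of the 4 groups had 3 libraries. The labels do not say that these came from separate cultures, so the p-values measure only the spread between these samples, which may be technical. Total counts were 25398920, 26198990 and 26435726 in the parental A375 libraries and 28718163, 29812686 and 26585099 in the resistant ones. In CHL1 they were 29230296, 27939832 and 26286297 in the parental libraries and 25567312, 28806186 and 28360044 in the resistant ones. The mitochondrially encoded share of counts was 1.88% ± 0.167 (SD, n = 3) in parental and 2.10% ± 0.174 (SD, n = 3) in resistant A375, and 3.17% ± 0.3 (SD, n = 3) and 3.01% ± 0.255 (SD, n = 3) in CHL1. Expression levels are given as normalised CPM (counts scaled to a common library size), mean ± SD over the 3 libraries of a group. Fold changes are resistant over parental on the log2 scale ± SE, with edgeR adjusted p-values. The SE was derived from the test, as the absolute log2 fold change divided by the square root of the quasi-likelihood F statistic.

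The first comparison asked which transcripts differed between palbociclib-resistant A375 cells and their parental line. Resistant A375 cells carried more mRNA of the S-phase cyclin CCNE1 and of the p53 targets CDKN1A and MDM2, and less mRNA of the retinoblastoma gene RB1 and of the proliferation antigen MKI67. Several collagens and the matrix protein fibronectin rose, while others such as COL5A1 (-1.06) fell. COL4A2 (-0.43) fell too, but lies in a falling block of chromosome 13. The matrix list (16 of 39 members up, 10 down) lost its call with an estimated correlation (adjusted p = 0.777). With a preset correlation the p53 target list rose (23 of 39 members up, 15 not called) and the interferon response (15 of 41 down), MHC class I presentation (7 of 17), hypoxia and glycolysis (13 of 31) and ATF4 and amino acid stress (12 of 29) lists fell. All 5 of these lists lost their calls with an estimated correlation (adjusted p = 0.697 for each). CCNE1 (ENSG00000105173) rose from 18.3 ± 1.71 to 30 ± 1.22 CPM (SD, n = 3), a log2 fold change of 0.71 ± 0.09 with an adjusted p of 0.00042, beside a median of 0.29 over its 20 nearest expressed genes. The first principal component, which held 79.9% of the variance, separated the 3 resistant from the 3 parental libraries.

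Among the 18 genes of the fixed panel, 6 passed the threshold in A375. The cell cycle inhibitor CDKN1A rose from 154 ± 6.81 to 257 ± 25.9 CPM (SD, n = 3), 0.74 ± 0.08 on the log2 scale. MDM2, the ubiquitin ligase that restrains p53, rose by 0.75 ± 0.07 with an adjusted p of 0.00014. Its 20 nearest expressed genes had a median of 0.05, although the adjacent gene named CPM rose by 1.51 (adjusted p = 0.00025). RB1, the target of the CDK4 and CDK6 kinases, changed by -0.55 ± 0.08 (adjusted p = 0.00081), beside a median of -0.48 over its 20 nearest expressed genes on chromosome 13. MKI67 changed by -0.49 ± 0.11 (adjusted p = 0.0092) and lies on chromosome 10 among genes that fell with it. MITF, the master regulator of melanocytes, changed by -0.48 ± 0.15 (adjusted p = 0.042), a call lost in 5 of the 6 fits that left out a library, without parental replicate 1, 2 or 3 or resistant replicate 1 or 3 (adjusted p from 0.0523 to 0.122). CDK4, CDK6, CCND1, CCND3, CCNE2, CDKN1B, CDKN2A, E2F1, PRMT5, MDM4, SOX10 and AXL did not pass, with log2 fold changes between -0.44 for SOX10 and 0.40 for CDKN2A. SOX10 passed with the replicate number as a block (-0.46, adjusted p = 0.015) and without a low-count filter (adjusted p = 0.037).

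**Figure D1:**
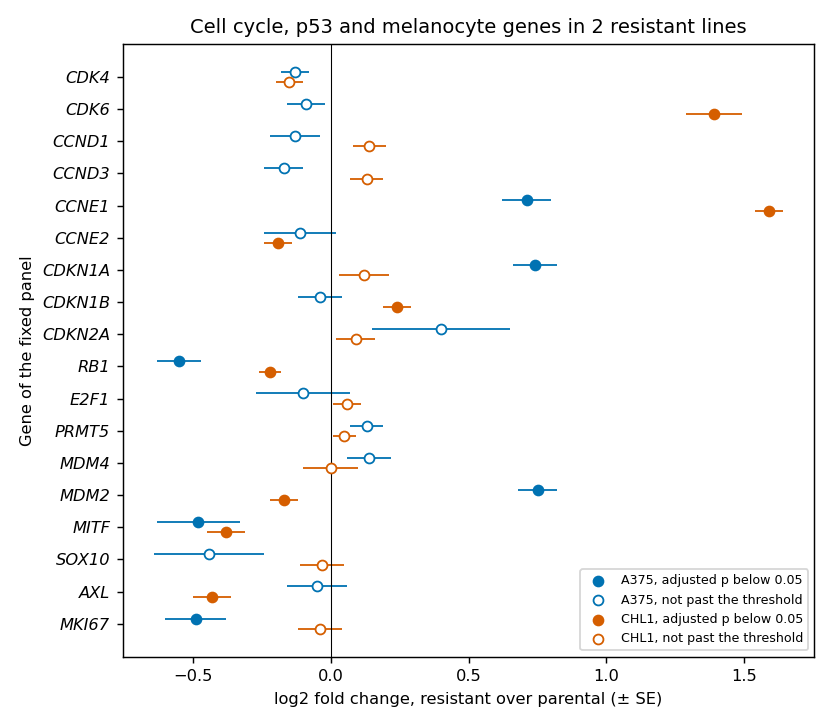
Log2 fold change of resistant over parental cells (horizontal axis) for the 18 panel genes in A375 and CHL1, with bars for the SE and filled symbols for adjusted p below 0.05. CCNE1 rose in both lines (0.71 and 1.59), CDK6 passed the threshold in CHL1 (1.39) and CDKN1A and MDM2 rose in A375 (0.74 and 0.75).

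The largest rises in A375 among genes of at least 10 CPM included secreted and surface proteins. FDCSP, a secreted peptide of follicular dendritic cells, went from 4 counts over the 3 parental libraries to 899 over the resistant ones, a ratio of 206 by depth (95% exact counting interval 80.2 to 758). The gelatinase MMP9 rose from 0.27 ± 0.167 to 17.6 ± 6.51 CPM (SD, n = 3) and the type I collagen chain COL1A2 from 0.399 ± 0.389 to 14.5 ± 1.4 CPM (SD, n = 3). The retinoic acid receptor RARB rose by 4.49 ± 0.27, the teneurin TENM1 by 3.86 ± 0.28, the protease inhibitor A2M by 3.74 ± 0.53 and the prostaglandin synthase PTGS2 by 3.52 ± 0.48. PPP4R3C (3.16), TRO (3.13) and the cornified envelope gene SPRR2D (3.04) completed the highest 10.

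The largest falls included EMC10 (ENSG00000161671), a subunit of the complex that inserts membrane proteins into the endoplasmic reticulum, which went from 44.8 ± 1.37 to 0.666 ± 0.0316 CPM (SD, n = 3). The long non-coding RNA UCA1 went from 57.2 ± 19.1 to 0.176 ± 0.0103 CPM (SD, n = 3) and the heparan sulfate sulfotransferase HS6ST2 from 35.8 ± 2.54 to 0.139 ± 0.0676 CPM (SD, n = 3). The splicing regulator MBNL3 went from 923 counts over the parental libraries to 5 over the resistant ones, a ratio of 201 by depth (95% exact counting interval 86.0 to 622). The peroxidase PXDN changed by -6.07 ± 0.31 and the protease TMPRSS15 by -6.92 ± 0.68, the latter from a spread-out parental level of 40.2 ± 29.9 CPM (SD, n = 3). MAGEA10 (-6.42), ARHGAP4 (-5.84), NLRP2 (-5.19) and RTL8B (-5.00) also fell, and reads of the MAGE family may be shared between its members. Of these 20 genes, 9 lie in blocks of neighbouring genes that shifted together on chromosomes 19 and X, and 6 of the 9 moved with their block. TENM1 rose in a falling block of chromosome X, and EMC10 and NLRP2 fell in a rising block of chromosome 19.

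Of 18086 genes tested in A375, 5111 passed an adjusted p of 0.05, 2426 higher and 2685 lower in resistant cells. With a 2-fold change as well, 1330 passed, 708 of them higher and 622 lower. Outside the blocks of neighbouring genes 4049 of the 5111 remained, 2055 higher and 1994 lower.

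The p53 target list rose in A375. Of 39 measured members 23 rose, 1 fell and 15 were not called, against 27 risen and 2 fallen when adjusted over the list alone (list adjusted p = 9.88e-09 and adjusted p = 0.697 with an estimated correlation). The apoptosis effector BAX rose from 109 ± 10.4 to 212 ± 12.4 CPM (SD, n = 3), the RNA-binding protein gene ZMAT3 by 0.86 ± 0.06, the nuclease gene AEN by 0.85 ± 0.06 and CYFIP2 by 1.68 ± 0.09.

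The G2/M and mitosis list rose, with 16 of 50 members up, 4 down and 30 not called, and 20 up and 4 down when adjusted over the list alone (list adjusted p = 0.00477 and adjusted p = 0.886 with an estimated correlation). The kinase AURKA rose by 0.26 ± 0.05, the kinesin KIF20A by 0.33 ± 0.06, CKS1B by 0.29 ± 0.06 and the phosphatase CDC25C by 0.42 ± 0.08. The 4 members that fell, BUB3, KIF11, CKAP2 and MKI67, all lie in falling blocks on chromosomes 10 and 13. The G1/S and DNA replication list rose with 8 of 53 members up, 3 down and 42 not called, the same counts as adjusted over the list alone (list adjusted p = 0.0475 and adjusted p = 0.886 with an estimated correlation). The G1/S call was lost in 3 of the 6 fits that left out a library (adjusted p up to 0.599), with fry (0.415) and with the 1 CPM filter (0.0569). The DNA ligase LIG1 rose by 0.69 ± 0.06 and the polymerase subunit POLD1 by 0.45 ± 0.06, both on a rising stretch of chromosome 19, and GINS1 rose by 0.36 ± 0.07 and the thymidylate synthase TYMS by 0.32 ± 0.06. The spliceosome core list rose with 7 of 36 members up, 1 down and 28 not called, also 7 and 1 when adjusted over the list alone (list adjusted p = 0.0471 and adjusted p = 0.886 with an estimated correlation). Its examples were SNRPD2 (0.43) and PRPF31 (0.47), both in the rising blocks of chromosome 19, SNRPB2 (0.56) and EFTUD2 (0.21), and outside the blocks the list had an adjusted p of 0.113. The spliceosome call was also lost in 3 of the 6 fits that left out a library (adjusted p up to 0.158), with fry (0.131) and with the 1 CPM filter (0.0569), and the G2/M call without resistant replicate 1 (0.057) and with fry (0.193).

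Matrix genes moved in both directions. The extracellular matrix list had 16 of 39 members up, 10 down and 13 not called, with 17 up and 10 down when adjusted over the list alone (list adjusted p = 0.0313, direction up, and adjusted p = 0.777 with an estimated correlation). Of the 10 that fell, 2 (COL4A2 and POSTN) lie in falling blocks of chromosome 13. Outside the blocks the list had an adjusted p of 0.0092 with the preset correlation. Collagen chain COL8A1 rose from 9.66 ± 1.14 to 71.9 ± 13.1 CPM (SD, n = 3), COL5A2 by 1.23 ± 0.07, COL6A3 by 1.67 ± 0.10 and COL6A2 by 1.61 ± 0.11. The fibroblast marker list, which shares collagens with the matrix list, had 7 of 13 members up, 2 down and 4 not called, the same when adjusted over the list alone (list adjusted p = 0.0313 and adjusted p = 0.697 with an estimated correlation). Besides COL1A2, the protease FAP rose by 3.46 ± 0.24, the proteoglycan LUM by 1.58 ± 0.20 and the receptor PDGFRA by 1.55 ± 0.21. COL3A1 rose by 2.06 on the log2 scale (0.181 to 0.765 CPM, adjusted p = 0.0043), while COL1A1 (5.15 to 6.03 CPM) and DCN (1.27 to 0.906 CPM) did not pass the threshold.

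The interferon response list fell, with 15 of 41 members down, 2 up and 24 not called, and 18 down and 2 up when adjusted over the list alone (list adjusted p = 0.0138 and adjusted p = 0.697 with an estimated correlation). IFI35 changed by -1.11 ± 0.11 and SAMD9 by -0.51 ± 0.06, while IFIT5 (-0.77) and IFIT3 (-0.65) lie with IFIT2 in the falling block of chromosome 10. MHC class I presentation fell with 7 of 17 members down, 1 up and 9 not called, and 8 down and 1 up when adjusted over the list alone (list adjusted p = 0.0169 and adjusted p = 0.697 with an estimated correlation). The immunoproteasome subunits PSMB8 (-0.57) and PSMB9 (-0.66, lost without resistant replicate 1 at adjusted p = 0.0537), the peptidase ERAP1 (-0.39) and the chaperone CALR (-0.33, in a falling block of chromosome 19) were among them.

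Hypoxia and glycolysis genes fell, with 13 of 31 down, 3 up and 15 not called, and 14 down and 5 up when adjusted over the list alone (list adjusted p = 0.015 and adjusted p = 0.697 with an estimated correlation). The glycolytic enzyme ALDOA fell by 0.59 on the log2 scale, from 1520 ± 75.4 to 1010 ± 37.8 CPM (SD, n = 3), and the angiogenic factor VEGFA changed by -0.62 ± 0.07. BNIP3 (-0.90) and PGAM1 (-0.66) lie in the chromosome 10 block. The ATF4 and amino acid stress list fell with 12 of 29 down, 4 up and 13 not called, and 14 down and 4 up when adjusted over the list alone (list adjusted p = 0.0169 and adjusted p = 0.697 with an estimated correlation). The secreted protein gene STC2 changed by -1.98 ± 0.20, ATF4 itself by -0.39 ± 0.05, the asparagine synthetase ASNS by -0.53 ± 0.07 and PHGDH, of serine synthesis, by -0.35 ± 0.06. The lysosome list fell with 17 of 47 down, 3 up and 27 not called, and 18 down and 5 up when adjusted over the list alone (list adjusted p = 0.0342 and adjusted p = 0.78 with an estimated correlation). The cathepsin CTSK changed by -3.01 ± 0.19, while IDS (-1.51), ATP6AP1 (-0.92) and the lipase LIPA (-0.91) lie in falling blocks of chromosomes X and 10, and outside the blocks the list had an adjusted p of 0.113.

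The remaining lists did not pass in A375. The nearest were neural and axon guidance genes (11 of 27 up, 3 down, adjusted p = 0.0518), keratinocyte and epithelial markers (5 of 9 down, 1 up, 0.0581), cytosolic chaperones (6 of 14 up, 3 down, 0.124) and mitochondrially encoded mRNAs (2 of 13 up, 0.131). Outside the blocks of neighbouring genes the chaperone (adjusted p = 0.00381), neural (0.0213) and keratinocyte (0.0369) lists passed, and with the replicate number as a block the chaperone (0.0348), keratinocyte (0.0348) and mitochondrial (0.0231) lists passed. Fry called drug efflux transporters (adjusted p = 0.029) and keratinocyte markers (0.0211), both downwards. The CDK4/6-RB axis had an adjusted p of 0.287, with CCNE1, CDKN1A and E2F5 up and CDKN1C, CDKN2D, RB1, RBL1 and E2F4 down. Of these, E2F5 ends a rising block of chromosome 8 (median 0.38), and RB1 lies among falling genes of chromosome 13. Receptor tyrosine kinases had an adjusted p of 0.323 (3 up, 7 down), and drug efflux transporters (2 up, 3 down), cholesterol synthesis and uptake (3 up, 6 down), MHC class II presentation (0 up, 0 down), inflammatory cytokines (7 up, 4 down), YAP/TAZ targets (1 up, 6 down), WNT and beta-catenin (5 up, 4 down) and ribosomal proteins (6 up, 7 down) each had 0.375. Adjusted p was 0.463 for Notch, 0.496 for ER chaperones and UPR, 0.52 for MITF and pigment cell genes and for TGF-beta targets, and 0.636 for MAPK pathway output. It was 0.731 for replication-dependent histones, 0.753 for fatty acid synthesis and handling, 0.778 for oxidative phosphorylation, 0.811 for immediate-early genes and 0.881 for the dedifferentiated melanoma state. It was 0.948 for the PRMT family and PRMT5 partners and 0.986 for NRF2 targets and apoptosis regulators. Median, mean and test differed in sign for TGF-beta targets, oxidative phosphorylation, fatty acid synthesis and handling, NRF2 targets, apoptosis regulators and Notch. Leukocyte markers (2 of 4 fell) and endothelial markers (0 of 4 called) had too few measured members to test.

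Of the 37 lists tested in A375, 11 were called with the preset correlation and 0 with an estimated correlation, and fry called 10, 8 of the 11 among them. Other splits of the same 6 libraries gave up to 14 called lists and 0 called genes. Each of them mixed the states unevenly, so it kept part of the resistance contrast and put the rest into the spread. These counts are therefore not a pure measure of chance.

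**Figure D2:**
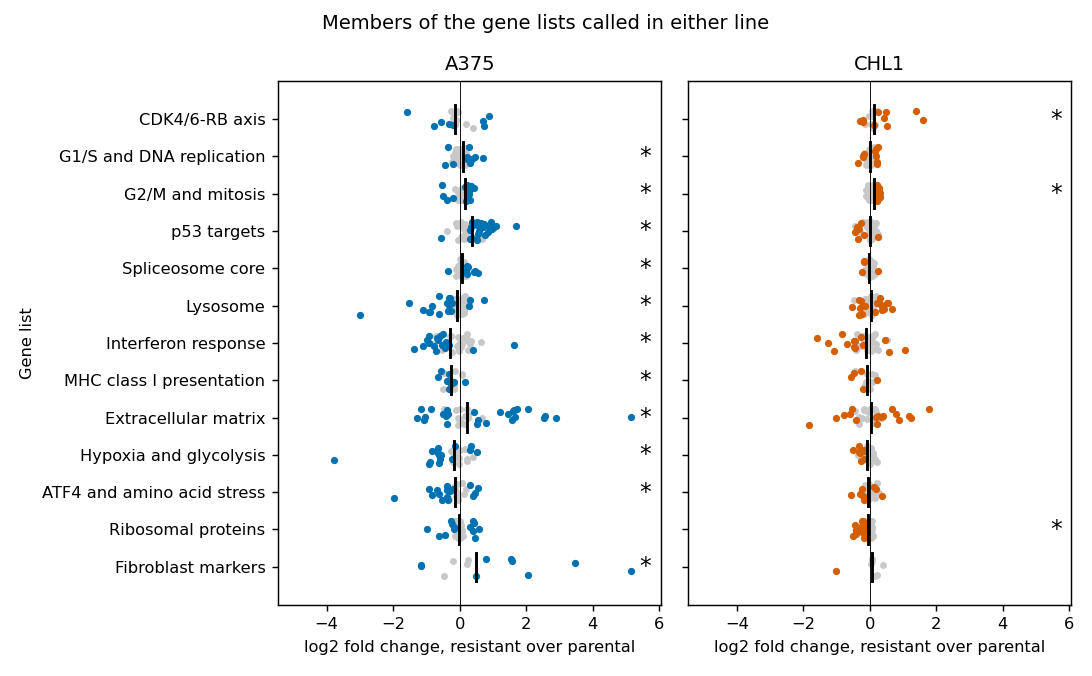
Log2 fold change (horizontal axis) of each measured member of the 13 lists called in at least 1 line, A375 on the left and CHL1 on the right, with coloured points for adjusted p below 0.05, black bars for medians and asterisks for lists called with the preset correlation. The p53 targets had a median of 0.38 in A375 and -0.01 in CHL1.

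The second comparison asked the same of CHL1. Resistant CHL1 cells carried 3.01-fold more CCNE1 and 2.61-fold more CDK6 mRNA than parental cells. CDK6 (ENSG00000105810), a direct target of palbociclib, rose from 13.4 ± 1.49 to 35.2 ± 4.44 CPM (SD, n = 3), and CCNE1 from 20.6 ± 0.484 to 62.1 ± 1.24 CPM (SD, n = 3). EMC10 fell here too, from 26.6 ± 2.29 to 0.872 ± 0.238 CPM (SD, n = 3). With a preset correlation the G2/M and mitosis list rose (18 of 50 members up) and the ribosomal protein list fell (14 of 52 down, 5 of these in blocks of chromosome 3). Both lost their calls with an estimated correlation (adjusted p = 0.924 for each) and with fry (0.133 and 0.12), and the ribosomal list also without resistant replicate 3 (0.144). The first principal component held 67.7% of the variance and separated resistant from parental libraries.

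In the panel 8 genes passed in CHL1. CCNE1 rose by 1.59 ± 0.05 (adjusted p = 4.9e-09), beside a median of 0.02 over its 20 nearest expressed genes, although the adjacent URI1 rose by 0.82. CDK6 rose by 1.39 ± 0.10 (adjusted p = 3.7e-06) beside a neighbour median of 0.03. The cell cycle inhibitor CDKN1B rose by 0.24 ± 0.05, and CCNE2 (-0.19), RB1 (-0.22), MITF (-0.38) and the receptor kinase AXL (-0.43) fell. MITF lies on chromosome 3, where 91.8% of the scanned genes fell in CHL1, with a median of -0.34. Its fall was thus close to that of its chromosome. MDM2 changed by -0.17 ± 0.05 (adjusted p = 0.044). That call was lost with RLE factors (0.0505), with library sizes alone (0.0608), with DESeq2 (0.0576) and in the fit to all 12 libraries (0.12). It was also lost without parental replicate 1 (0.163) or 2 (0.137) or resistant replicate 2 (0.146) or 3 (0.157). CCNE2 lost its call without parental replicate 1 (adjusted p = 0.0661) or resistant replicate 3 (0.0715). CDK4, CCND1, CCND3, CDKN1A, CDKN2A, E2F1, PRMT5, MDM4, SOX10 and MKI67 did not pass, with log2 fold changes from -0.15 for CDK4 to 0.14 for CCND1. CDK4 passed with the replicate number as a block (adjusted p = 0.0405), without a low-count filter (0.0285) and with the 1 CPM filter (0.0455), and CCND1 passed without a low-count filter (0.0344).

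**Figure D3:**
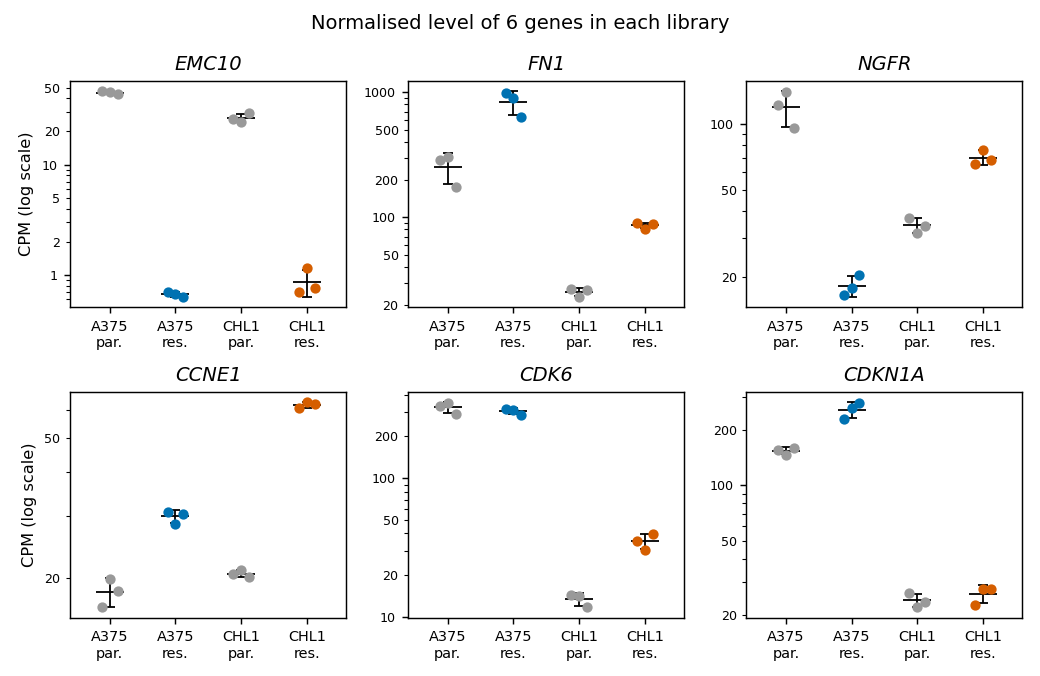
Normalised CPM (vertical axis, log scale) of 6 genes in each of the 12 libraries, with a bar for the mean and whiskers for the SD of 3 libraries. EMC10 fell below 2 CPM in all 6 resistant libraries, while NGFR fell in A375 (119 to 18.2 CPM) and rose in CHL1 (34.5 to 70.2 CPM).

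The highest rise among genes of at least 10 CPM in CHL1 was in fibronectin, FN1 (ENSG00000115414), from 25.3 ± 1.91 to 86.3 ± 4.42 CPM (SD, n = 3). The secreted glycoprotein FSTL1 rose by 1.75 ± 0.10 although it lies in a falling stretch of chromosome 3. The protocadherin PCDH10 rose by 1.65 ± 0.08, the small heat shock protein HSPB8 by 1.45 ± 0.09, the laminin chain LAMA2 by 1.34 ± 0.09 and the oncostatin M receptor OSMR by 1.24 ± 0.07. TRIM48 (1.44), which has close paralogs that may share its reads, and the potassium channel partner KCNIP1 (1.38) rose as well.

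The urotensin peptide gene UTS2 fell most in CHL1, from 1072 counts over the parental libraries to 3 over the resistant ones, a ratio of 354 by depth (95% exact counting interval 121 to 1720). EMC10 changed by -4.91 ± 0.14 and the bone morphogenetic protein BMP7 by -4.72 ± 0.14, from 15.9 ± 0.215 to 0.6 ± 0.144 CPM (SD, n = 3). PPARG, a nuclear receptor of lipid metabolism, changed by -3.06 ± 0.12, beside a neighbour median of -0.34 on chromosome 3. The adjacent TIMP4 changed by -2.0 (adjusted p = 8.4e-05). The falls of PDZRN4 (-3.58), TMEM273 (-2.85), the splicing factor RBFOX1 (-2.80), the kinase DCLK1 (-2.42), the potassium channel KCNQ3 (-2.33) and the ketone body enzyme OXCT1 (-2.22) completed the 10.

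Of 17219 genes tested in CHL1, 3645 passed an adjusted p of 0.05, 1569 higher and 2076 lower in resistant cells. With a 2-fold change 296 passed, 90 higher and 206 lower. Outside the blocks of neighbouring genes 3103 of the 3645 remained, 1540 higher and 1563 lower.

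The CDK4/6-RB axis list rose in CHL1, with 7 of 22 members up, 3 down and 12 not called, and 8 up and 4 down when adjusted over the list alone (list adjusted p = 0.0221 and adjusted p = 0.924 with an estimated correlation). Besides CCNE1 and CDK6, the inhibitors CDKN2C (0.51 ± 0.07) and CDKN1C (0.48 ± 0.09) rose, and both of these restrain the cell cycle. G2/M and mitosis genes rose, with 18 of 50 up, 0 down and 32 not called, and 25 up and 1 down when adjusted over the list alone (list adjusted p = 7.12e-06 and adjusted p = 0.924 with an estimated correlation). BIRC5 rose by 0.29 ± 0.05, ANLN by 0.30 ± 0.05, the checkpoint kinase BUB1 by 0.23 ± 0.04 and the kinesin KIF4A by 0.27 ± 0.05. Ribosomal protein genes fell, with 14 of 52 down, 0 up and 38 not called, as also when adjusted over the list alone (list adjusted p = 0.00435 and adjusted p = 0.924 with an estimated correlation). RPL15 (-0.49), RPL32 (-0.43), RPL29 (-0.46) and RPL14 (-0.42) lie with RPL24 in the falling blocks of chromosome 3, and outside the blocks the list had an adjusted p of 0.0359. Without resistant replicate 3 the ribosomal list lost its call (adjusted p = 0.144).

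The remaining lists did not pass in CHL1. The nearest were replication-dependent histones (4 of 11 down, 0 up, adjusted p = 0.101), the interferon response (11 of 40 down, 3 up, 0.126), mitochondrially encoded mRNAs (4 of 13 down, 0 up, 0.183), hypoxia and glycolysis (8 of 27 down, 0 up, 0.19), and fatty acid synthesis and handling (7 of 22 down, 3 up, 0.19). The histone list passed with the 1 CPM filter (adjusted p = 0.0211) and outside the blocks (0.0461). Fry called 5 of these remaining lists, all downwards: fatty acid synthesis and handling (adjusted p = 0.00199), the interferon response (0.00588), p53 targets (0.0251), histones (0.0251) and receptor tyrosine kinases (0.0313). The extracellular matrix list had 11 up and 6 down of 35 (adjusted p = 0.229). Adjusted p was 0.306 for apoptosis regulators, 0.327 for MITF and pigment cell genes (2 up, 5 down), and 0.329 for oxidative phosphorylation, neural and axon guidance genes, and immediate-early genes. It was 0.499 for p53 targets (1 of 35 up, 7 down), receptor tyrosine kinases (0 up, 5 down), cholesterol synthesis and uptake, and MHC class I presentation. It was 0.529 for MAPK pathway output, 0.565 for G1/S and DNA replication and the spliceosome core, 0.594 for leukocyte markers, and 0.645 for the lysosome (10 up, 8 down) and keratinocyte and epithelial markers. It was 0.801 for the dedifferentiated melanoma state and ATF4 and amino acid stress, 0.825 for ER chaperones and UPR, NRF2 targets and cytosolic chaperones, and 0.857 for Notch. It was 0.903 for drug efflux transporters and fibroblast markers, and 0.926 for the PRMT family and PRMT5 partners, MHC class II presentation, inflammatory cytokines, TGF-beta targets and YAP/TAZ targets. Median, mean and test differed in sign for the PRMT family and PRMT5 partners, MHC class II presentation, TGF-beta targets, ER chaperones and UPR, cytosolic chaperones, fibroblast markers, and WNT and beta-catenin. WNT and beta-catenin had 0.983, and endothelial markers (0 of 3 called) had too few measured members to test.

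Of the 38 lists tested in CHL1, 3 were called with the preset correlation and 0 with an estimated correlation. Other splits of the 6 CHL1 libraries gave up to 10 called lists and 0 called genes, and they too kept part of the resistance contrast.

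The third comparison asked whether the lines changed alike. The log2 fold changes of the 15975 genes tested in both lines had a Pearson r of 0.024 and a Spearman rho of 0.031 across genes, which are not independent replicates, and 40 of the 99 pairs of splits with regrouped libraries gave an absolute r as large. FN1 rose alike in both lines, by 1.72 ± 0.22 in A375 and 1.77 ± 0.07 in CHL1. EMC10 fell in both, as did the coagulation initiator F3 (-1.08 and -1.13) and the collagen chain COL5A1 (-1.06 and -1.83). The neurotrophin receptor gene NGFR moved apart, by -2.71 ± 0.14 in A375 and 1.02 ± 0.07 in CHL1.

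At 2-fold, 30 genes changed in the same direction in both lines and 30 in opposite directions. Of these, 11 rose in both where 1.59 would overlap by independence (two-sided Fisher's exact test across genes, p = 4.07e-07, adjusted over 8 overlaps 5.43e-07) and 19 fell in both against 2.82 (p = 5.04e-11, adjusted 1.34e-10). The opposite overlaps were as far above independence, 22 up in A375 and down in CHL1 against 3.71 (exact p = 1.57e-11, adjusted 8.8e-11) and 8 the other way against 1.21 (p = 2.53e-05, adjusted 2.89e-05). With the 10 CPM floor the named genes numbered 1 rising, 3 falling and 4 opposite, the last being NGFR, the actin regulator partner NCKAP5 (up in A375 and -1.12 in CHL1), the glutathione peroxidase GPX3 (-1.33 and 1.05) and LUM (1.58 and -1.01).

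**Figure D4:**
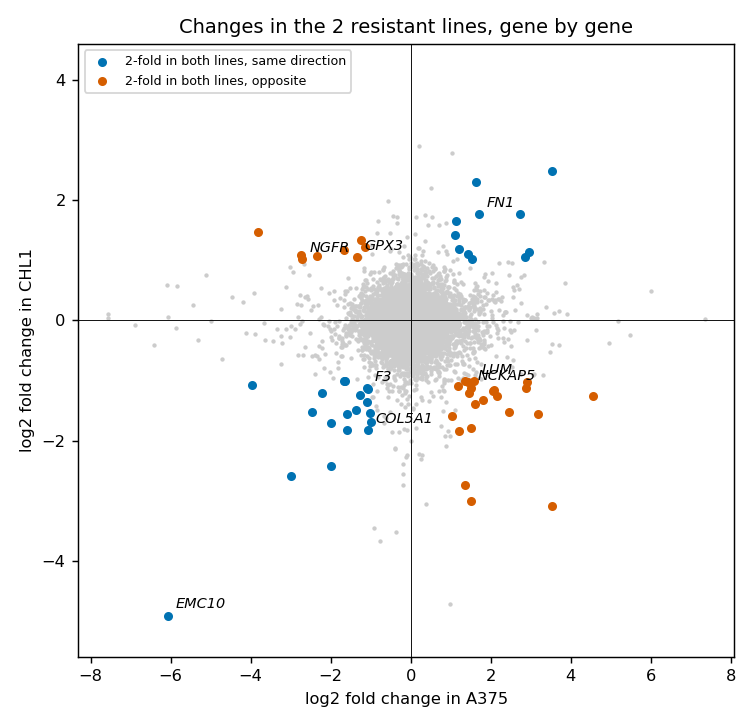
Log2 fold change of each of the 15975 genes tested in both lines, A375 on the horizontal and CHL1 on the vertical axis, with genes called at 2-fold in both lines coloured by direction. The 30 same-direction and 30 opposite genes lie on either side, and EMC10 is at -6.06 and -4.91.

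In the test of the difference itself, 4536 of 19241 genes changed differently in the lines, 2251 more towards a rise in A375 and 2285 in CHL1, and 1317 of them by at least 2-fold. Each line had a single resistant derivative, made over 7 months in A375 and 3 months in CHL1. Line, length of exposure and the particular derivation therefore cannot be told apart in these differences. The CCNE1 rise was smaller in A375 by a log2 difference of -0.88 ± 0.10 (adjusted p = 1.71e-05), and CDK6 differed by -1.48 ± 0.14 (adjusted p = 3.55e-06). MDM2 differed by 0.92 ± 0.09 and CDKN1A by 0.61 ± 0.13, both higher in A375, and RB1 by -0.33 ± 0.09. The differences of CCND3 (-0.30), CDKN1B (-0.29) and MKI67 (-0.45) passed with adjusted p of 0.0384, 0.0371 and 0.0494, and lost their calls in 9, 8 and 9 of the 12 fits that left out a library, with adjusted p up to 0.135, 0.142 and 0.152. The CCND3 difference was also lost with RLE factors (adjusted p = 0.061), the 1 CPM filter (0.0539) and DESeq2 (0.0539), and that of MKI67 with RLE factors (0.0603), library size alone (0.0502), the 1 CPM filter (0.0614) and limma-voom (0.051). The difference of SOX10 passed with the replicate number as a block (-0.44, adjusted p = 0.0437) and that of AXL with DESeq2 (0.39, adjusted p = 0.0486). Among lists, p53 targets changed more towards a rise in A375 (adjusted p = 3.18e-07 and adjusted p = 0.613 with an estimated correlation), and the CDK4/6-RB axis in CHL1 (adjusted p = 0.0214 and adjusted p = 0.613 with an estimated correlation). The spliceosome core (0.0485) and mitochondrially encoded mRNAs (0.0309) were higher in A375 and the lysosome (0.0309) in CHL1, each with adjusted p = 0.943 with an estimated correlation. For MITF no difference between the lines was detected (-0.10 ± 0.18, adjusted p = 0.74), though its A375 call was lost in 5 of the 6 fits that left out a library and its CHL1 call in the fit to all 12 libraries (adjusted p = 0.0728). In CHL1 MITF also lies on chromosome 3, whose scanned genes had a median of -0.34.

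Genes that lie next to each other on a chromosome often shifted together, which was looked for after the values were seen. In A375, 259 scanned genes of chromosome 10 from AP3M1 to CYP2E1 had a median log2 fold change of -0.57 and 93.4% of them fell, while their median in CHL1 was 0.04. The end of chromosome X from AMOT on (152 genes) had a median of -0.89, chromosome 13 a median of -0.41, and the stretch from TMEM223 to EHBP1L1 on chromosome 11 a median of -0.54. On chromosome 19, 4 blocks between COL5A3 and ZNF253 fell (medians -0.37 to -0.45) and 5 blocks between PROSER3 and TRIM28 rose (0.44 to 0.56). In CHL1, 522 genes of chromosome 3 from the gene CHL1 to WWTR1 had a median of -0.38 and 93.5% fell, beside a median of -0.04 in A375, and a further 91 genes ending at LMLN had -0.28. The 18 blocks of A375 held 1062 calls, 20.8% of all calls among 8.68% of the tested genes, and the 5 blocks of CHL1 held 542 calls, 14.9% among 5.3%. The blocks were built from genes that shifted together in these data, so an excess of calls inside them is set by that selection.

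**Figure D5:**
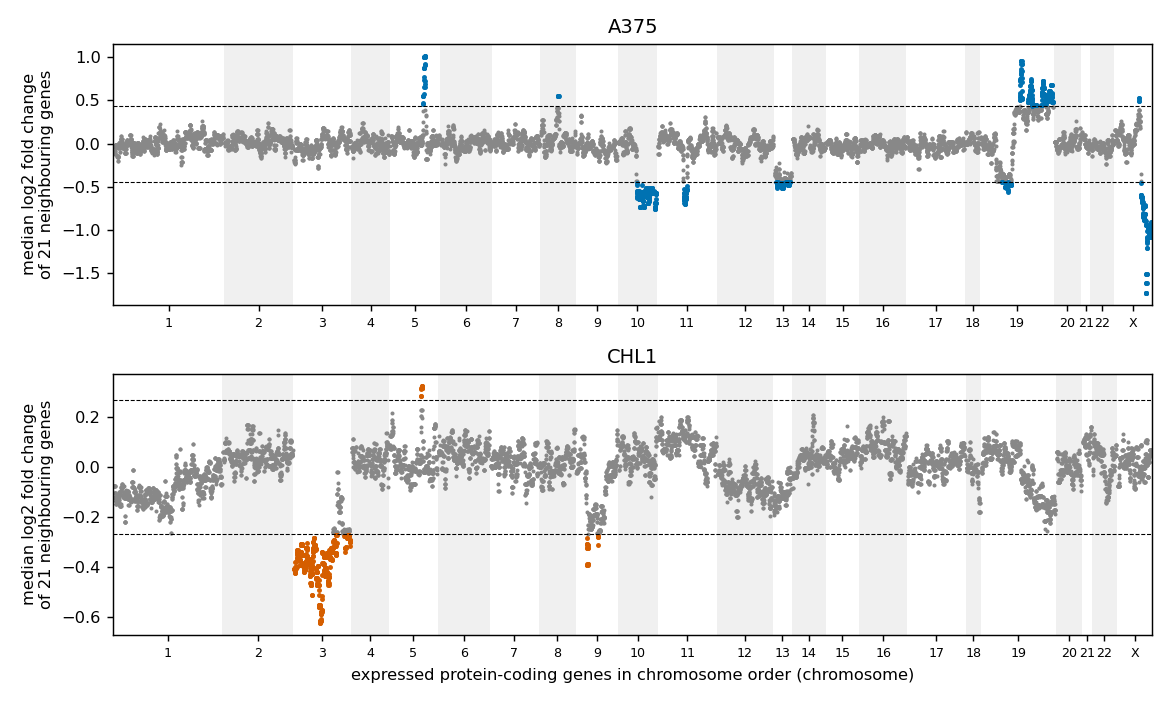
Median log2 fold change of windows of 21 neighbouring expressed genes (vertical axis) in chromosome order (horizontal axis), with dashed lines at the threshold from shuffled gene orders, 0.44 in A375 and 0.27 in CHL1, and coloured points beyond it. In A375 windows on chromosomes 5, 8, 10, 11, 13, 19 and X passed, and in CHL1 windows on chromosomes 3, 5 and 9.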

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

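The tests of blocks of neighbouring genes, of EMC10 and of the matrix and fibroblast genes in this part were chosen after the results were seen, while the splits of the libraries were planned.

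The change of 4536 genes differed between A375 and CHL1 by the interaction test, in which line, length of exposure and the single derivation per line cannot be told apart. In 60 of the 200 possible within-line splits of the libraries, the real one included, 1 gave as many genes. The highest other split gave 2413 genes and kept the A375 groups as labelled while it regrouped CHL1. A regrouped line carries its own resistance change in the spread between its libraries, which lowers the count, so these splits decide nothing about 2 lines that changed alike.

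For single genes the interaction test found these differences, A375 minus CHL1 in log2 fold change. NGFR differed by -3.74, GPX3 by -2.39, LUM by 2.58 and NCKAP5 by 2.61, each with opposite calls in the lines. EMC10 differed by -1.15 and COL5A1 by 0.76, although both fell in both lines. The resistant level of EMC10 was below 1 CPM in each line, 0.666 CPM in A375 and 0.872 CPM in CHL1. Its parental levels were 44.8 CPM in A375 and 26.6 CPM in CHL1, so the difference also reflects where each line started. CDK6 differed by -1.48, CCNE1 by -0.88, RB1 by -0.33, CCND3 by -0.30, CDKN1B by -0.29 and MKI67 by -0.45. MDM2 differed by 0.92 and CDKN1A by 0.61.

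Among gene lists the difference had an adjusted p of 3.18e-07 for p53 targets, 0.0214 for the CDK4/6-RB axis, 0.0485 for the spliceosome core, 0.0309 for the lysosome and 0.0309 for mitochondrially encoded mRNAs, under the preset correlation. All 5 lost their calls with an estimated correlation, with adjusted p of 0.613 for the first 2 and 0.943 for the other 3.

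Blocks of neighbouring genes shifted together in each resistant derivative, 18 in A375 and 5 in CHL1. A trend with GC content or gene length is argued against as the whole cause, since at least 83.1% of every block median was left after that trend was taken off. A mix-up of libraries between the lines is argued against too, though not a wrong label within a line: each resistant library correlated with its own parental libraries by at least 0.114 more than with those of the other line. A candidate explanation is a change in the dose of a stretch of chromosome, gained or lost in the derivative or present in a subclone of the parental line. In 20 of the 21 blocks outside the protocadherin clusters at least 80% of the genes above 10 CPM moved in the block's direction while the other line stayed within 0.20 of 0, but the blocks were built from genes that moved together, so that share decides nothing. Tested genes that the scan had left out, and that overlap no scanned gene, followed their block in 161 of 239 cases in A375 and 88 of 128 in CHL1. This was at least 18.1 percentage points more often in both lines than such genes outside the blocks. DNA copy number was not measured, so this stays a hypothesis.

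EMC10 was the only gene called in both lines that fell or rose at least 8-fold in the same direction, with 1136 to 1171 counts per parental and 17 to 20 per resistant A375 library, and 683 to 762 against 18 to 33 in CHL1. Loss of the whole surrounding stretch is argued against, because the median of the 20 nearest genes lay at least 4.78 above the EMC10 log2 fold change in both lines. Of the 3 genes annotated as overlapping EMC10, 1 had counts. Its summed counts went from 20 in parental to 0 in resistant A375 and from 18 to 0 in CHL1. That argues against reads moved to this overlapping gene. Reads moved to a neighbouring gene stay open by the test as first written, which required that no nearby gene gain more than 25% of the EMC10 loss in either line. C19orf48P gained 103% of that loss in A375 and MYH14 gained 48.0% in CHL1. The same gene did not gain in both lines to that extent, as C19orf48P changed by -8.11% of the loss in CHL1 and MYH14 by 15.3% in A375. This second form was tried only after the first had returned 103%, and had for a time replaced it as evidence against this explanation, so it was given no weight and the first form was put back. EMC10 lies in a rising block of chromosome 19 in A375. Its 20 nearest expressed genes had a median log2 fold change of 0.35 there, and the adjacent POLD1 rose from 121 to 166 CPM. In A375 the first form therefore cannot tell moved reads from the shift of the block. A change confined to the gene, such as a small deletion, silencing or a selected subclone, stays open, as untested.

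In resistant A375, 16 of 39 matrix genes rose and 10 fell, and 7 of 13 fibroblast markers rose and 2 fell, with lists called under the preset correlation and lost with an estimated one (adjusted p = 0.777 and 0.697). Fibroblasts in the cultures are argued against as the whole cause: COL1A1, COL3A1 and DCN gained a median of 4.1% of the CPM that COL1A2 gained. LUM, which gained 99% of it, and COL3A1, which passed the threshold with a log2 fold change of 2.06 from 0.181 CPM, went with that explanation, as did FAP (0.206 to 2.32 CPM) and PDGFRA (1.55 to 4.55 CPM). CHL1 cells in the A375 cultures are argued against too, since 35 genes high in CHL1 and at the floor in parental A375 changed by a median of -0.0033% of their CHL1 level. These tests leave open, as a hypothesis, that the resistant A375 cells themselves may express this part of the matrix genes, or that a subclone which does so was selected.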

How the results depend on the processing

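Restricting the counts to genes outside the blocks was chosen after the data were seen, and the other alternatives were planned. The totals of called genes, of genes that differed between the lines and of genes changed alike kept their size within 1.5 times under RLE factors, library size alone, both low-count filters, DESeq2, limma-voom and the genes outside the blocks. Parts of them moved further: the CHL1 rises at 2-fold went from 90 to 57 with the 1 CPM filter and to 137 without a low-count filter, the opposite genes from 30 to 19 with the 1 CPM filter, and the genes risen in both lines from 11 to 6 with that filter, 7 with DESeq2 and 6 outside the blocks. By construction, an adjusted p of 0.01 lowered the called genes to 2978 in A375 and 1973 in CHL1, and the test against a 2-fold change lowered the 2-fold counts to 421 and 71. Dropping the size requirement raised the genes changed alike from 30 to 652, beside 581 opposite, where independence would give 471 and 464. The correlation was 0.063 over genes of at least 10 CPM, 0.038 with the 1 CPM filter, 0.010 without a low-count filter and 0.019 outside the blocks, and the cause was not tested. With an estimated correlation 0 lists were called in A375 and 0 in CHL1. The 1 CPM filter left 6 lists in A375, without G1/S, spliceosome, lysosome, matrix (0.0569 each) and fibroblast (0.0755). Fry called 6 in CHL1 but kept only 1 of the 3 main ones, without G2/M (0.133) and ribosomal proteins (0.12), and in A375 it lost G1/S (0.415), G2/M (0.193) and spliceosome (0.131). On ranks the calls of the CHL1 CDK4/6-RB axis (0.0698) and the A375 lysosome (0.103), matrix (0.113) and fibroblast (0.099) lists were lost. The cause was not tested.

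With each library left out in turn the called genes ranged from 3782 to 4738 in A375 and from 2634 to 3297 in CHL1, and at 2-fold from 1249 to 1392 and from 280 to 307. The genes that differed between the lines ranged from 3760 to 4519, the genes changed alike from 24 to 32, and r from 0.014 to 0.029. Called lists ranged from 7 to 15 in A375, with 7 without resistant replicate 1, and from 2 to 5 in CHL1, with 2 without resistant replicate 3 and 5 without parental replicate 2. In A375 the p53, interferon, MHC class I, hypoxia and ATF4 lists kept their calls in all 6 of these fits. The G1/S list lost its call without parental replicate 1 (0.599) or resistant replicate 1 (0.114) or 2 (0.0615), and the spliceosome list without the same libraries (0.158, 0.116 and 0.055). The G2/M list lost it without resistant replicate 1 (0.057), the lysosome list without resistant replicate 2 (0.0647), the matrix list without parental replicate 2 (0.0662) or resistant replicate 1 (0.0576), and the fibroblast list without parental replicate 2 (0.0701). Calls were gained for 5 lists in A375: neural and axon guidance without parental replicate 1 or 3 or resistant replicate 2 (0.0221 to 0.0321), keratinocyte without parental replicate 1 or 2 or resistant replicate 3 (0.0225 to 0.0329), chaperones and mitochondrial mRNAs without parental replicate 3 (0.0257) or resistant replicate 2 (0.0236), and MHC class II without parental replicate 3 (0.00866). In CHL1 the interferon and histone lists were gained without parental replicate 2 (0.0463), and mitochondrial mRNAs without parental replicate 3 (0.00657) or resistant replicate 1 (0.00234). Single genes gained a call as well: in A375 CCND3 without parental replicate 1 (0.0266) and CDKN2A without parental replicate 3 (0.0445), and in CHL1 CCND1 without resistant replicate 1 (0.033) and CDK4 without parental replicate 2 (0.0163). The difference of AXL between the lines passed without A375 parental replicate 3 (0.00259), as did that of CDKN2A (0.0445). The differences of CCND3, CDKN1B and MKI67 held without A375 resistant replicate 1; that of CCND3 held also without A375 parental replicate 1 or CHL1 resistant replicate 1, that of CDKN1B without A375 parental replicate 2 or 3 or CHL1 parental replicate 1, and that of MKI67 without A375 parental replicate 2 or CHL1 resistant replicate 2. No called result changed direction under the alternatives run. Of the fold changes of named genes, in fits other than those that left out a library, 0 calls were lost in A375 and 7 in CHL1. Among these were CCNE2 (0.254), CDKN1C (0.165), MDM2 (0.12) and MITF (0.0728) in the fit to all 12 libraries.

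Residuals of libraries with the same replicate number correlated by 0.51, 0.49 and -0.03 in A375 and by 0.34, 0.00 and 0.17 in CHL1. Between different numbers they correlated by -0.58 to 0.17 in A375 and by -0.29 to 0.17 in CHL1. Residuals were taken from the mean of each group of 3 libraries, so these correlations depend on each other, and they were not tested. Resistant and parental A375 libraries of replicates 1 and 2 may share part of their spread, which the main fits did not model. The labels do not say what a replicate number shares, so the main fits did not pair the libraries. With the replicate number as a block 6307 genes were called in A375 and 4305 in CHL1, 1356 and 294 at 2-fold, 5364 differed between the lines, 29 changed alike, r was 0.023, and 14 and 3 lists were called. Depth limits the genes near the floor, such as UTS2, FDCSP and MBNL3, whose fitted folds depend on the prior count.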

Other observations

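The block values in this part came from the scan made after the values were seen, while the splits of the libraries were planned. On chromosome 5 the block from ZMAT2 to FCHSD1, which holds 42 protocadherin genes among 48, had a median log2 fold change of 0.61 in resistant A375. In resistant CHL1 the block from PCDHA1 to ARAP3, with 27 protocadherin genes among 33, had a median of 0.29.

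Some chromosomes without blocks had smaller shifts of their median in CHL1. It was -0.09 on chromosome 1 (70.7% of genes lower), -0.07 on chromosome 12 (67.2% lower) and -0.11 on chromosome 13 (73.5% lower). On chromosome 11 it was 0.09 (72.9% higher), on chromosome 16 0.07 (70.1% higher) and on chromosome 21 0.10 (71.9% higher). How far along a chromosome such a shift reached was not tested. These medians were not tested.

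In A375 several groups without a called list held large single changes. Among inflammatory genes the collagenase MMP1 rose from 16.3 to 132 CPM, the adhesion molecule ICAM1 from 25.2 to 60.4 CPM and IL1A from 4.75 to 24.7 CPM, while IL24 fell from 37.7 to 9.55 CPM. Among keratinocyte and epithelial markers KRT14 fell from 23.3 to 4.55 CPM and SFN from 5.5 to 0.776 CPM. The cell adhesion gene L1CAM fell in both lines, from 216 to 41.1 CPM in A375 and from 41.0 to 22.1 CPM in CHL1, and lies in the falling block of chromosome X in A375. In CHL1 the pigment enzyme DCT fell from 43.0 to 18.4 CPM. These genes were chosen after their values were seen.

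For the counts within a line the 10 splits of 6 libraries are too few for a share under 0.05. Each split other than the real one also mixed the states unevenly. It kept part of the resistance contrast and put the rest into the spread, so calling 0 genes was nearly fixed in advance. Neither the counts of these splits nor their r are a pure measure of chance. The real split, 1 of the 10, called 5111 genes in A375 against 0 as the highest other, and 1330 against 0 at 2-fold. In CHL1 it called 3645 against 0, and 296 against 0 at 2-fold. For lists the real split called 11 in A375 against 14 as the highest other, with 3 of the 10 splits calling as many, and 3 in CHL1 against 10, with 9 of the 10 calling as many. For genes changed alike at 2-fold, 1 of the 100 pairs of splits gave 30, the real one, and the highest other gave 0. Every regrouped split of a line called 0 genes, so the other pairs had to give 0 and these splits decide nothing about agreement between the lines. For the correlation between the lines, 41 of the 100 pairs, the real one included, gave an absolute r of at least 0.024 and the highest other gave 0.119, so chance cannot be excluded.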
